A study of Rattus norvegicus with 8 samples.

How the data were processed

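RNA was measured in 8 libraries of INS-1 cells, 1 per group. Total RNA was taken with Trizol and a column, mRNA was isolated and libraries were made with NEBNext Ultra kits, per the labels' protocols. Reads were aligned with TopHat2 and expression was computed with Cuffdiff on the rn5 rat genome, per the submitters' processing notes. Versions, the gene annotation, the use of strand and Cuffdiff's library scaling were not given in the sources used here. The deposited values are FPKM, in which the authors divided fragments by transcript length and by library size. A scaling that differs between libraries would shift all folds that use one of them. The authors deposited 2 tables, each with 4 libraries, cut to genes whose forskolin over DMSO ratio was above 2 in the reference condition, as tested on the values. The tables were treated separately and no level was compared across them.

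Each library was assigned to its group by its title and each column to its library by name. Names were matched to a RefSeq gene table of another rat assembly, GRCr8, used for names only, and no coordinates are given. Of the glucose names 1223 matched a symbol, 22 a gene ID, 86 a synonym and 13 nothing, and of the A-CREB names 524, 9, 31 and 2. Fosb appears in the files under a LOC identifier and was named through its gene ID. MafA appears with stray quote marks. A single name of the glucose table was only digits, and this gene was counted but not named. Short genes such as Mir343 have FPKM values that few reads can move far, and microRNA genes can share reads with a host gene.

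A fold was log2((forskolin + 0.1)/(DMSO + 0.1)). The change was the fold in the second condition minus that in the reference condition, and the DMSO ratio was the second condition over the reference. Medians have 95% distribution-free intervals from order statistics. These give the uncertainty of the median over genes, taken as if independent, and not between cultures. With 1 library per group no test between conditions was run and no p-value is given. No fold of a single gene was formed where a library listed it at 0, since a 0 can be a failed estimate. A 0 in some library was found for 75 genes of the glucose table and 44 of the A-CREB table.

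Before the data were examined, 13 gene lists, the rule for named genes and most of the alternative settings were fixed. Named genes were the 10 largest reference folds, the 8 lowest and 5 highest changes, the 4 highest and 4 lowest DMSO ratios, up to 4 most expressed members of each list, and a short set of known cAMP targets. Pkib, of that set, was not listed in either table. Some genes that the rule names are not reported here. For a list with at least 5 members the median was placed among 10000 random lists of the same size drawn from the same table by deciles of mean expression, and the percentile is the percent of random lists with a median as low or lower. This was done for 10 lists in the glucose table and 6 in the A-CREB table. Some genes belong to several lists, so the results of the lists are not independent. Since a list's change follows its reference fold, the percentile was also computed with matching on that fold, a choice made after seeing the data.

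Depth was estimated from genes with a mean below 1 FPKM, where ratios between libraries pile up on ratios of small whole numbers of reads (tolerance 2%). The worth of 1 read in each library was the step that gathered the most ratios, set to the centre of those ratios. From 93 genes at 1 read in 2.8 mM DMSO, 1 read was worth 0.0589 FPKM at the median gene, and from 109 genes without virus, 0.139 FPKM. It varies with gene length. The centring was added after the first estimate had been seen and lowered the share of ratios on the steps from 53.9% to 51.9% in the glucose table and from 77.6% to 73.6% in the A-CREB table. Leaving genes listed at 0 out of the single-gene alternatives and of the genes singled out for opposite folds was also decided after their values had been seen. It took out Il15, Lif, Mgst3 and Rxfp3 of the A-CREB table and Mir343 and Ucn3 of the glucose table.

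The functions were tested on simulated data. With a simulated median change of -0.70, the recovered median was -0.71 with 1344 genes, the number in the glucose table. It was -0.72 with 566 genes, the number in the A-CREB table. This recovery checks the calculation only. It does not show that the measured medians are free of effects of the listing by reference fold, of few reads or of the pseudocount. Alternatives were pseudocounts of 1 and 0.01, means of at least 1 or 5 FPKM, thresholds of 1.5-fold and 3-fold, genes at least 2-fold in the reference condition, other list matching, and, added after seeing the data, genes with a 0 left out, reference folds of at least 8, and lists without genes at 0 or with a mean below 1 FPKM. Intervals in the tests of explanations came from order statistics or 2000 bootstrap resamples over genes. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.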

Results

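INS-1 cells, an insulin-secreting rat insulinoma line used as a model of the pancreatic beta cell, were profiled by RNA sequencing in 8 libraries. Of these, 4 came from cells kept for 3 days in 2.8 or 20 mM glucose and then given 10 uM forskolin or its vehicle DMSO for 2 h. The other 4 came from cells at 11 mM glucose, either without virus or exposed for 2 days to an adenovirus for A-CREB, again with forskolin or DMSO. Forskolin activates adenylyl cyclase and so raises cAMP, CREB is a transcription factor switched on by cAMP-dependent protein kinase, and A-CREB is a dominant-negative protein that blocks CREB. The series addressed how glucose exposure and CREB activity alter gene regulation by cAMP in beta cells. Each group had 1 library, so no difference between conditions had a replicate check and none was tested. The values below describe these libraries.

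Expression was given as FPKM (fragments scaled by transcript length and library size) in a glucose table of 1344 genes and an A-CREB table of 566 genes, which were handled separately. Both tables list only genes whose forskolin value was over 2 times the DMSO value in a reference condition, which was 2.8 mM glucose in the first and no virus in the second. The lowest ratio listed was 2.00 in both. Genes without such a ratio were not analysed here. Folds are on the log2(FPKM + 0.1) scale, which understates the folds of weakly expressed genes. Total read numbers were not given in the sources used here. The spacing of the low values gave an estimate of depth. A value of 1 FPKM stood for about 16.99 reads in the 2.8 mM DMSO library and about 7.20 reads in the no-virus DMSO library. Relative to its DMSO reference, estimated depth was 0.742 for 2.8 mM forskolin, 1.22 for 20 mM DMSO and 0.827 for 20 mM forskolin. It was 0.906 for no-virus forskolin, 1.08 for A-CREB DMSO and 1.35 for A-CREB forskolin.

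The first comparison asked whether the forskolin response differed between 3 days at 20 mM and 3 days at 2.8 mM glucose. This table has no library at another glucose level. A lowered response at 20 mM and a raised one at 2.8 mM could therefore not be told apart. The 10 genes with the largest folds at 2.8 mM all had lower folds at 20 mM. Of these, 3 were in the CREB early response list (Nr4a3, Fosl2 and Fosb), and the others were Fam46b, Rgs2, Actn2, Rxfp3, Gprc5a, Ccnd1 and Tac1. The forskolin level itself was higher at 20 mM for Rxfp3 and Gprc5a and lower for the other genes of this set. Nr4a3, an orphan nuclear receptor, went from 0.256 FPKM in DMSO to 263 FPKM in forskolin at 2.8 mM (739-fold) and from 2.02 to 143 FPKM at 20 mM (67.6-fold). Fosl2, a subunit of the AP-1 transcription factor, went from 3.65 to 1544 FPKM at 2.8 mM (412-fold) and from 31.0 to 728 FPKM at 20 mM (23.4-fold). Its log2 ratio of 20 mM over 2.8 mM was 3.05 in DMSO and -1.08 in forskolin, so its lower fold went largely with a higher DMSO level. Fosb, another AP-1 subunit, kept more of its fold, at 357-fold and 184-fold. Its DMSO levels were 0.352 FPKM at 2.8 mM and 0.270 FPKM at 20 mM. These and the 2.8 mM DMSO level of Nr4a3 are of few reads, so the size of their folds depends on the pseudocount. Rgs2, a regulator of G protein signalling, was at 226 FPKM in forskolin at 2.8 mM and 38.8 FPKM at 20 mM, with folds of 229.9 and 23.6. Over the whole table, the median log2 forskolin fold was 1.45 at 2.8 mM (interquartile range 1.13 to 2.09) and 0.73 at 20 mM (0.29 to 1.34). The fold was lower at 20 mM in 1226 of 1344 genes (91.2%) and higher in 118. It was lower by more than 1.5 times in 881 genes and higher by more than 1.5 times in 28. At least a 2-fold value was reached by 1192 genes at 2.8 mM, by 500 at 20 mM (37.2%) and by 484 in both. Without the pseudocount all 1344 genes pass at 2.8 mM, since they were listed for this. At 20 mM 520 then pass, with genes at 0 in DMSO not counted. In 174 genes the forskolin value at 20 mM lay below the DMSO value.

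The median change of the log2 fold, 20 mM minus 2.8 mM, was -0.81 (95% order-statistic interval over genes -0.85 to -0.77). Among genes with a mean of at least 1 FPKM it was -0.68 in the 714 genes below 4-fold at 2.8 mM, -1.15 in the 182 genes of 4-fold to below 8-fold, and -1.64 in the 153 genes of 8-fold or more. Of those 153 genes, 146 had a lower fold at 20 mM and 143 still reached 2-fold. Because genes were listed by their fold at 2.8 mM, chance alone would tend to place their folds lower in any other condition. The count at 20 mM depended on the threshold, with 784 genes at 1.5-fold and 257 at 3-fold.

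**Figure D1:**
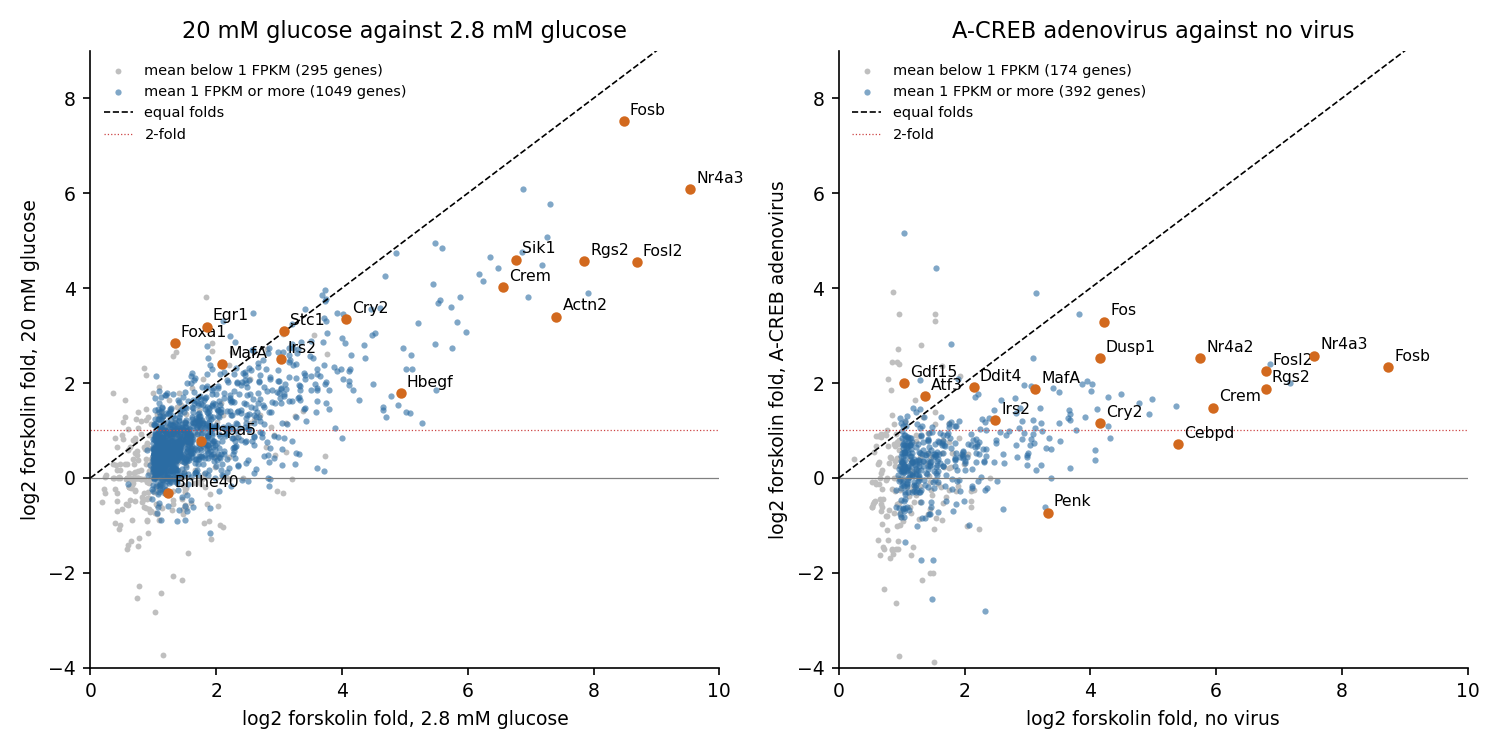
Log2 forskolin fold in the reference condition (x axis) against the log2 fold in the other condition (y axis), 1 point per gene, for 20 mM against 2.8 mM glucose (left) and A-CREB adenovirus against no virus (right), with grey for a mean below 1 FPKM, orange for named genes, a black dashed line at equal folds and a red dotted line at 2-fold. Of 1344 genes 1226 have a lower fold on the left and 522 of 566 on the right, and Mir343, listed at 0 in 20 mM DMSO, lies above the left axis.

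Of the 28 listed members of the CREB early response list, 22 had a lower fold at 20 mM and 6 a higher one, and 26 still reached 2-fold. Their median change was -1.48, and none of 10000 random lists of the same size and expression had a median as low. These genes also had high folds at 2.8 mM, and among random lists matched on that fold the same median lay at percentile 45.6. Crem, which encodes the CREB antagonist ICER as well as activators, went from 7.73 to 738 FPKM at 2.8 mM and from 23.0 to 375 FPKM at 20 mM. Nr4a1, a nuclear receptor of the same family as Nr4a3, had folds of 58.9 and 13.99. Ppargc1a, a coactivator of mitochondrial genes, had folds of 44.4 and 7.05, and Fos had folds of 116 and 27.2. Ppargc1a was at 1.63 and 76.7 FPKM in DMSO and forskolin at 2.8 mM and at 7.23 and 51.6 FPKM at 20 mM. Egr1, a zinc finger transcription factor, went the other way, with 3.60-fold at 2.8 mM and 9.10-fold at 20 mM.

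All 16 listed cAMP signal attenuators had a lower fold at 20 mM, 9 of them by more than 1.5 times, with a median change of -0.92 at percentile 25.4, or 47.8 when matched on the 2.8 mM fold. Sik1, a kinase that restrains CREB coactivators, went from 4.66 to 517 FPKM at 2.8 mM and from 11.0 to 269 FPKM at 20 mM. Prkar1a, a regulatory subunit of protein kinase A, had folds of 3.36 and 1.66. The phosphodiesterase gene Pde4b had folds of 2.26 and 1.898. Of 9 MAPK phosphatases and feedback genes, 8 had a lower fold, with a median change of -0.97 at percentile 27.9, or 70.7 when matched on the 2.8 mM fold. Dusp1, a phosphatase of MAP kinases, was at 441 FPKM in forskolin at 2.8 mM and 68.8 FPKM at 20 mM.

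In the neuropeptide and granin list, 5 of 6 members had a lower fold, with a median change of -1.62 at percentile 1.72. Cartpt, the precursor of the CART peptide, had folds of 62.9 and 8.40, and Tac1, the precursor of substance P, had folds of 124 and 14.03. The granin Vgf stayed closer, at 4.35 and 3.46, and the glycoprotein hormone gene Stc1 had 8.44 and 8.50. In the growth factor and cytokine list, 8 of 10 members had a lower fold, with a median change of -1.44 at percentile 1.96. Their median log2 DMSO ratio was -0.56 at percentile 0.52. Hbegf, a ligand of the EGF receptor, was already at 56.1 FPKM in DMSO at 20 mM against 3.98 FPKM at 2.8 mM, and its folds were 3.45 and 30.5. Igf1r, a receptor of insulin-like growth factor, had 3.03-fold at 2.8 mM and 4.40-fold at 20 mM. Matched on the 2.8 mM fold, these lists lay at percentiles 32.1 and 22.6.

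Of 14 unfolded protein and stress response genes, 12 had a lower fold at 20 mM and 11 had a lower DMSO level. The median change of fold was -1.08 at percentile 3.92, or 32.8 when matched on the 2.8 mM fold. The median DMSO ratio was -0.62 on the log2 scale, at percentile 0.16. Hspa5, the main chaperone of the endoplasmic reticulum, went from 1076 to 3641 FPKM at 2.8 mM and from 463 to 792 FPKM at 20 mM. Gadd45g, a stress-induced gene, had folds of 4.36 and 1.48. All 8 members of the hypoxia and glycolysis list had a lower fold, with a median change of -1.19 at percentile 6.04, or 4.84 when matched on the 2.8 mM fold (5.28 with genes at 0 left out). The glucose transporter gene Slc2a1 had folds of 4.84 and 1.55. Vegfa, Bhlhe40 and Ddit4 of the hypoxia and glycolysis list are also in other lists. The 7 ion channel and transporter genes also all had lower folds, with a median change of -1.28 at percentile 7.94, or 15.6 when matched on that fold. The potassium channel gene Kcnk1 had folds of 2.99 and 2.04. Of 6 circadian clock genes 5 had a lower fold, with a median change of -1.06 at percentile 20.9, or 50.2 when matched on that fold. Among these 6, Nfil3, Per1, Bhlhe40 and Per2 are also in the CREB early response list. Per1, a clock gene that responds to CREB, had folds of 12.1 and 4.58.

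Of the 8 listed beta cell genes 6 had a lower fold, with a median change of -0.65 at percentile 75.6, or 79.8 when matched on the 2.8 mM fold. The median log2 DMSO ratio was -0.61 at percentile 0.64. Ucn3, a peptide hormone gene at 1.33 and 3.20 FPKM at 2.8 mM and listed at 0 in both 20 mM libraries, entered these values through the pseudocount. With genes at 0 left out 5 of 7 genes had a lower fold, and the median DMSO ratio was -0.26 at percentile 7.48. MafA, a transcription factor of mature beta cells, was at 149 FPKM in DMSO and 639 FPKM in forskolin at 2.8 mM, and at 14.6 and 77.3 FPKM at 20 mM. Its forskolin fold was 4.27 at 2.8 mM and 5.27 at 20 mM. Irs2, an adaptor of the insulin receptor, had folds of 8.20 and 5.65. Of the interferon list 3 genes were present, of which Ddx58 and Irf7 had lower folds and Rsad2 a higher one. The ChREBP and glucose response list had too few listed members for a percentile. None of the 24 genes of the fixed list of markers of other cell types was in either table, and other such markers were not searched for.

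Among genes with a mean of at least 1 FPKM, the lowest changes were those of Fosl2 (-4.14), Ntsr1 (-4.11), Fam46b (-4.02), Actn2 (-4.01), Cd83 (-3.71), Penk (-3.65), Prdm1 (-3.64) and Calca (-3.56). This order depends on the pseudocount. With a pseudocount of 1 the changes were -4.60 for Fam46b, -3.87 for Fosl2, -3.62 for Cd83 and -3.52 for Actn2. They were -2.76 for Ntsr1, -2.31 for Prdm1, -2.29 for Calca and -1.72 for Penk. Ntsr1 encodes a neurotensin receptor and Calca the precursor of calcitonin. Among the highest changes with a fold were those of the transcription factor genes Foxa1 (1.499) and Egr1 (1.34), and of LOC500035 (1.10). Mir343, a microRNA gene, was listed at 0 in the 20 mM DMSO library and at 367 FPKM with forskolin, and no fold was formed.

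The second arm of the glucose comparison set the DMSO libraries side by side. Itpkb, an inositol phosphate kinase, was at 59.5 FPKM at 2.8 mM and 3.40 FPKM at 20 mM. Mertk, a receptor tyrosine kinase, was at 35.9 and 2.21 FPKM. The monocarboxylate transporter gene Slc16a1 was at 0.874 FPKM at 2.8 mM and 12.0 FPKM at 20 mM, and the uroplakin gene Upk3a at 0.0866 and 5.50 FPKM. Dennd2c was at 0.0601 and 2.01 FPKM. With 1 read worth 0.0589 FPKM at the median gene in 2.8 mM DMSO, the 2.8 mM levels of Upk3a and Dennd2c are of few reads. Over all 1344 genes the median log2 DMSO ratio was 0.14 (95% interval over genes 0.08 to 0.18), with 379 genes higher and 214 lower at 20 mM by more than 1.5 times. With a pseudocount of 1 the median was 0.066. In forskolin, 1081 genes had a lower level at 20 mM, and the median log2 ratio was -0.67. As genes were listed by their 2.8 mM forskolin over DMSO ratio, chance alone would tend to raise the DMSO median and lower the forskolin median.

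**Figure D2:**
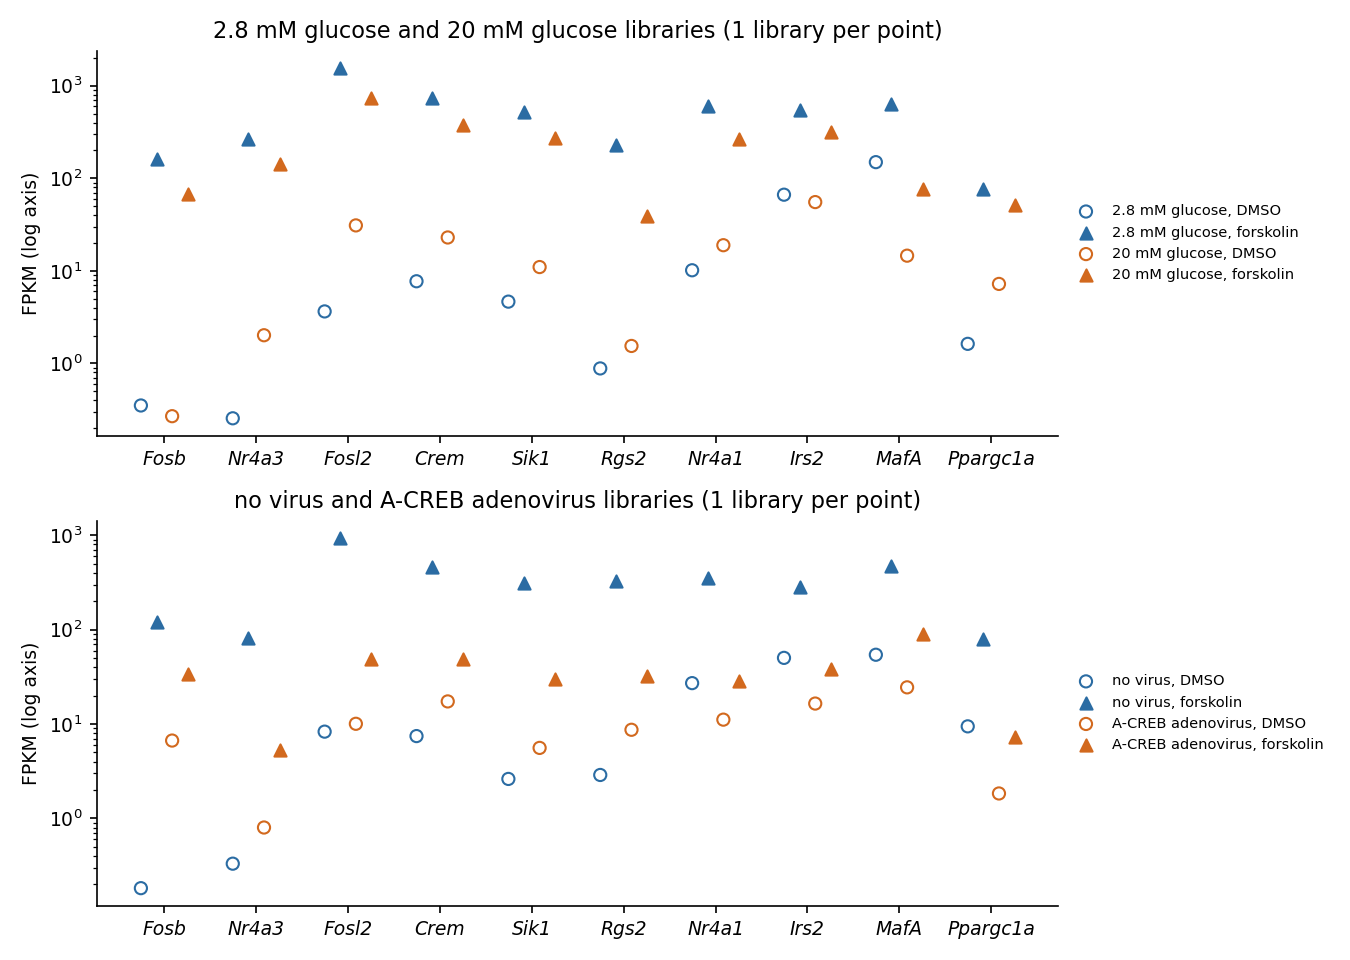
FPKM on a log axis of 10 genes in the 4 libraries of the glucose table (top) and of the A-CREB table (bottom), 1 library per point, with DMSO as open circles, forskolin as filled triangles, the reference condition (2.8 mM glucose or no virus) in blue and the other (20 mM glucose or A-CREB) in orange. Crem reached 738 FPKM with forskolin at 2.8 mM and 375 at 20 mM, and 465 FPKM without virus and 48.7 with A-CREB.

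The second comparison asked how A-CREB altered the forskolin response at 11 mM glucose. Since the control cells had no virus, infection and A-CREB could not be separated in any of its values. The 10 genes with the largest folds without virus all had lower folds with A-CREB, and 7 of them were in the CREB early response list. Fosb went from 0.183 to 120 FPKM without virus (424-fold) and from 6.69 to 34.1 FPKM with A-CREB (5.04-fold). With 1 read worth 0.139 FPKM at the median gene in no-virus DMSO, the 424-fold value rests on few reads. Klf4, a zinc finger transcription factor, had folds of 144 and 4.002. Nr4a3 was at 81.3 FPKM in forskolin without virus and 5.28 FPKM with A-CREB, with folds of 189 and 5.96. Over the table, the median log2 forskolin fold was 1.34 without virus (interquartile range 1.04 to 1.93) and 0.36 with A-CREB (-0.15 to 0.84). The fold was lower with A-CREB in 522 of 566 genes (92.2%) and higher in 44. It was lower by more than 1.5 times in 447 and higher by more than 1.5 times in 18. At least 2-fold was reached by 455 genes without virus, by 108 with A-CREB (19.1%) and by 95 in both. Without the pseudocount all 566 genes pass in the no-virus condition, since they were listed for this. With A-CREB 102 then pass, with genes at 0 in DMSO not counted. In 170 genes the forskolin value lay below DMSO with A-CREB.

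The median change of log2 fold with A-CREB was -1.20 (95% interval over genes -1.31 to -1.13). Among genes with a mean of at least 1 FPKM it was -0.97 in the 267 genes below 4-fold without virus, -1.72 in the 64 genes of 4-fold to below 8-fold and -2.64 in the 61 genes of 8-fold or more. In the group of 61, 60 had a lower fold and 41 still reached 2-fold. As in the glucose table, genes were listed by their reference fold. At a mean of at least 5 FPKM, 252 genes reached 2-fold without virus and 63 with A-CREB.

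Of 23 CREB early response genes, 22 had a lower fold with A-CREB, 21 by more than 1.5 times. Their median change was -2.19 at percentile 0.01 among random lists, or 54.7 when matched on the fold without virus. Cebpd, a transcription factor of the C/EBP family, had folds of 41.9 and 1.64, and Crem had folds of 61.6 and 2.80. Atf3, the 1 exception, had 2.57-fold without virus and 3.29-fold with A-CREB. All 7 cAMP signal attenuators had a fold lower by more than 1.5 times, with a median change of -1.67 at percentile 17.8, or 75.7 when matched on the fold without virus. This median is that of a small list, and with genes of a mean below 1 FPKM left out, here Pde4b, it was -3.06 at percentile 0.03, or 1.86 matched. Sik1 had folds of 115 and 5.30, and Rgs2 had 330.0 FPKM in forskolin without virus against 32.3 FPKM with A-CREB. All 3 clock genes had a lower fold, among them Cry2 with 17.9 and 2.23.

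In the growth factor and cytokine list 6 of 8 members had a lower fold with A-CREB. The median change was -2.41 at percentile 0.56, or 2.62 when matched on the fold without virus. It lies between Areg and Ptgs2, at 0.294 and 0.173 FPKM in no-virus DMSO, so it rests on few reads, and with the 7 genes of a mean of at least 1 FPKM the matched percentile was 7.11. Tgfb2, a growth factor of the TGF-beta family, had folds of 15.1 and 2.42, and Hbegf had 19.5 and 3.25. Gdf15, a stress-induced cytokine, went the other way, with 2.06-fold without virus and 3.996-fold with A-CREB. Lif and Cxcl1 were each listed at 0 in 1 A-CREB library and entered the median through the pseudocount, and Cxcl1 counted as higher only through it. With genes at 0 left out, 5 of 6 members had a lower fold. The median was again -2.41, at percentile 0.56, or 0.91 when matched, and still lay between Areg and Ptgs2. Lif was at 1.37 and 7.28 FPKM without virus, and at 0.602 FPKM in DMSO and 0 in forskolin with A-CREB. All 4 neuropeptide genes had a lower fold, among them Stc1 with 12.7 and 2.70 and Tac1 with 4.30 and 1.61.

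The unfolded protein and stress response genes kept most of their forskolin fold. Of 6 members 5 had a lower fold, and 1 of them, Gadd45b, by more than 1.5 times. The member with a higher fold was Atf3, which is also the exception of the CREB early response list. The median change of -0.29 lay at percentile 99.8 among random lists and at the same percentile when matched on the fold without virus. Ddit4, an inhibitor of mTOR signalling, had folds of 4.41 and 3.75. Ppp1r15a, a phosphatase subunit that reverses eIF2-alpha phosphorylation, had folds of 3.07 and 2.43, and Ddit3, also known as CHOP, had 2.01 and 1.80. All 8 MAPK phosphatase and feedback genes had a lower fold, with a median change of -0.97 at percentile 75.2, or 98.0 when matched on the fold without virus. Dusp1 had folds of 17.7 and 5.78. The 3 genes of the hypoxia list and the 3 of the ion channel list all had lower folds. Pfkfb3, a glycolytic regulator, had 4.04 and 1.13, and Slc16a1 had 2.95 and 1.289. The single listed genes of the interferon and ChREBP lists, Irf7 and Acacb, had lower forskolin than DMSO values with A-CREB.

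Of 5 beta cell genes 4 had a lower fold and 4 a lower DMSO level with A-CREB. The median change was -1.25 at percentile 43.4, or 74.3 when matched on the fold without virus, and the median log2 DMSO ratio was -1.14 at percentile 0.31. Irs2 was at 50.3 and 283 FPKM without virus and at 16.5 and 38.4 FPKM with A-CREB. MafA was at 54.2 and 474 FPKM without virus and at 24.5 and 90.2 FPKM with A-CREB. Pdx1, a transcription factor of beta cell identity, had folds of 2.09 and 2.13.

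**Figure D3:**
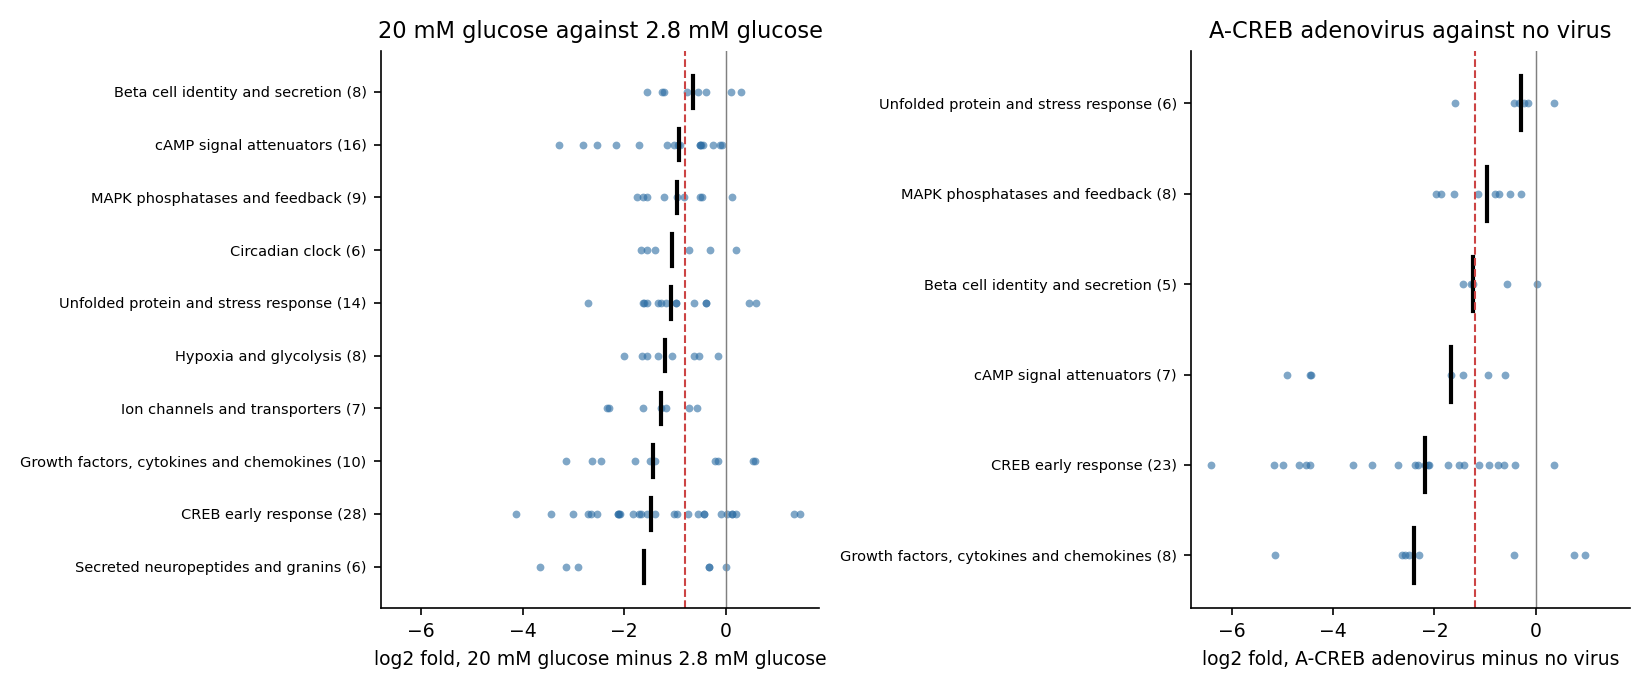
Change of the log2 forskolin fold (x axis) for 20 mM minus 2.8 mM glucose (left) and A-CREB minus no virus (right), 1 blue point per gene, for each list with at least 5 listed members (their number in brackets), with black bars at list medians, a red dashed line at the median of all genes in the table and a grey line at 0. The CREB early response median was -1.48 on the left and -2.19 on the right, and the stress response median was -1.08 and -0.29.

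Of genes with a mean of at least 1 FPKM and no value of 0, the lowest changes with A-CREB were those of Fosb (-6.40), Klf4 (-5.17), Nr4a3 (-4.98), Rgs2 (-4.91), Cebpd (-4.67), Fosl2 (-4.53) and Crem (-4.46). Fosb and Nr4a3 were at 0.183 and 0.332 FPKM in no-virus DMSO, levels of few reads. Their changes, and so this order, depend on the pseudocount. The highest were those of Nfkbiz, an inducible regulator of NF-kappaB (1.03), Gdf15 (0.96) and the cytokine subunit gene Il23a (0.76). Il15 and Mgst3 were listed at 0 in the A-CREB DMSO library and at 2.03 and 3.50 FPKM in A-CREB forskolin.

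Between the DMSO libraries of the A-CREB table, the potassium channel subunit gene Kcnf1 was at 0.676 FPKM without virus and 46.6 FPKM with A-CREB. Mlf1 was at 0.613 and 26.7 FPKM, Tp73, of the p53 family, at 0.0612 and 3.07 FPKM, and Fosb at 0.183 and 6.69 FPKM. The no-virus levels of Tp73 and Fosb are of few reads. Ppargc1a was at 9.46 and 1.84 FPKM, and Rxfp3, a relaxin family receptor, at 0.454 FPKM and 0. The median log2 DMSO ratio was 0.36 (95% interval over genes 0.22 to 0.45), with 218 genes higher and 98 lower by more than 1.5 times. It was 0.58 among genes with a mean below 1 FPKM, 0.74 at 1 to below 5 FPKM and 0.014 at 5 FPKM or more. In forskolin, 444 genes had a lower level with A-CREB, and the median log2 ratio was -0.90. As genes were listed by their no-virus forskolin over DMSO ratio, chance alone would tend to raise the DMSO median and lower the forskolin median.

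The tables shared 324 genes, 24.1% of the glucose table and 57.2% of the A-CREB table. Among them were Fosb, Nr4a3, Fosl2, Crem, Sik1, Rgs2, Irs2 and MafA. The fold was lower in both second conditions in 284 genes, lower at 20 mM alone in 9, lower with A-CREB alone in 29 and lower in neither in 2. Of all listed genes, 91.2% had a lower fold at 20 mM and 92.2% with A-CREB. Most shared genes would thus be lower in both without any relation between the changes. At least 2-fold was reached at 20 mM but not with A-CREB by 168 genes, with A-CREB but not at 20 mM by 10, in both by 70 and in neither by 76. Across genes, which are not independent replicates, the reference log2 folds of the tables had a Pearson correlation of 0.72 and a Spearman correlation of 0.60. The changes of log2 fold had 0.30 and 0.28, and the DMSO ratios had 0.12 and 0.13.

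**Figure D4:**
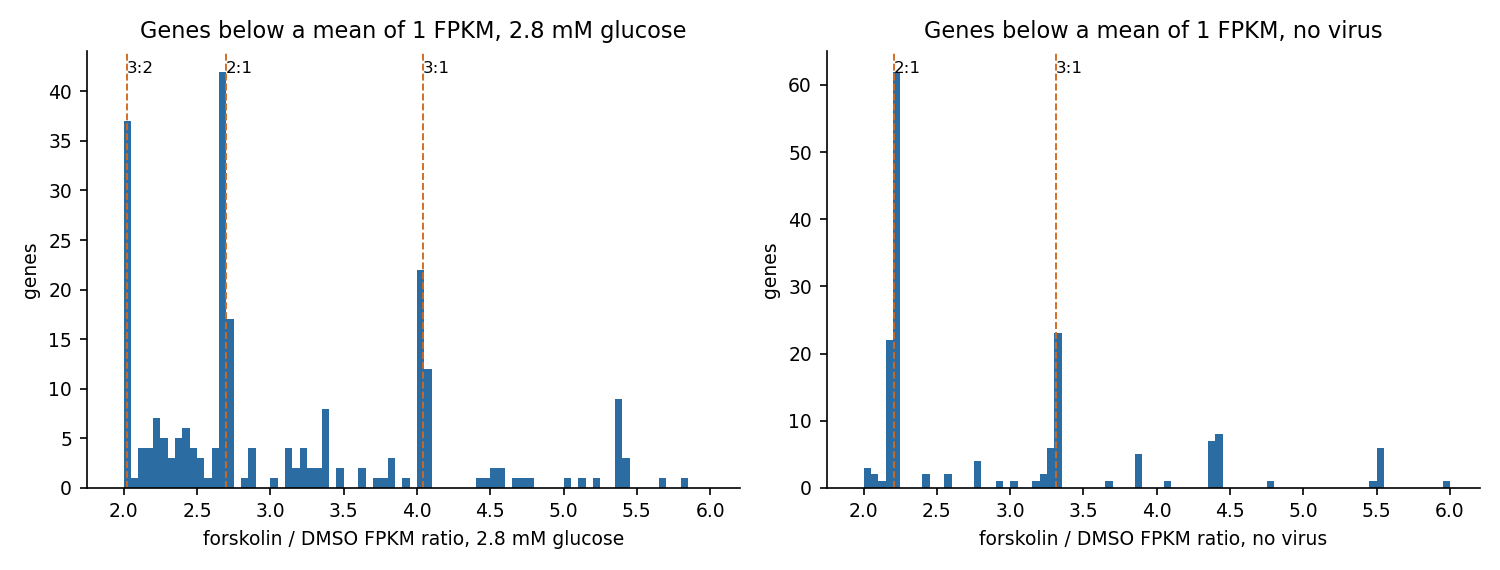
Number of genes (y axis) by forskolin over DMSO FPKM ratio in the reference condition (x axis, bins of equal width), for genes with a mean below 1 FPKM in the glucose table (left, 295 genes) and the A-CREB table (right, 174 genes), with dashed lines at ratios that small whole numbers of reads would give and 54 and 11 genes beyond the axis. On the left 59 genes lie on the 2:1 ratio of 2.69, and on the right 80 lie on that of 2.21.

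Weakly expressed genes made up part of both tables. A mean below 1 FPKM was found for 295 genes (21.9%) of the glucose table and 174 (30.7%) of the A-CREB table. In them, 51.9% and 73.6% of the reference forskolin ratios lay within 2% of ratios that small whole numbers of reads would give.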

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

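The genes here were singled out among the named genes because forskolin was above DMSO in the reference condition and below it in the other, with 1 library on each side. In all, 174 genes of the glucose table and 170 of the A-CREB table lay below DMSO in the second condition. The difference was not tested for any of them. The tests of whole-read ratios were chosen after the result was seen, and the other tests before.

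At 20 mM glucose the log2 forskolin fold was -0.32 for Bhlhe40, a transcriptional repressor of the clock. It was -0.89 for Ddx58, an RNA sensor of the antiviral response, and -0.080 for Irf7, an interferon regulatory factor. With A-CREB it was -0.998 for Acacb, an acetyl-CoA carboxylase, and -0.29 for Irf7. It was -0.73 for Penk, the precursor of enkephalins, and -0.26 for Tp73. Without virus Tp73 was at 0.0612 and 0.204 FPKM and Acacb at 0.199 and 0.487 FPKM, levels of a few reads. Penk and Irf7 were at 0.670 and 0.951 FPKM in no-virus DMSO, where 1 FPKM stood for about 7.20 reads at the median gene. Irf7 was at 1.31 FPKM in A-CREB DMSO. The folds of Penk and Irf7 in the A-CREB table may therefore also rest on few reads. Lif also went from higher to lower, but it was listed at 0 in A-CREB forskolin, so no fold is given.

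Forskolin folds were lower at 20 mM than at 2.8 mM glucose in 1226 of 1344 genes. The choice of genes by their 2.8 mM fold would by itself give lower folds at 20 mM, so 125 genes were picked instead by a 4-fold response without virus at 11 mM, in other libraries. Of these 118 were in the glucose table, and with the 7 missing ones counted as higher at 20 mM the median change was -1.15 (95% interval -1.47 to -0.75), which argues against this choice as the whole cause. One scaling factor on a library would move all genes alike, but the change was lower by -0.65 (-1.06 to -0.28) in the 60 genes with at least 8-fold without virus than in the 163 genes of 2-fold to below 4-fold. A part due to scaling, a difference between single cultures and an effect of glucose, which was not tested, stay open.

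Forskolin folds were lower with A-CREB than without virus in 522 of 566 genes. Genes picked by a 4-fold response at 2.8 mM glucose numbered 335, of which 210 were in the A-CREB table. With the 125 missing ones counted as higher, the median change was -0.83 (95% interval -1.02 to -0.52), which argues against the choice of genes as the whole cause. Between 120 genes with at least 8-fold and 83 genes of 2-fold to below 4-fold at 2.8 mM, the change differed by -1.01 (-1.24 to -0.70), which argues against a single scaling factor as the whole cause. A part due to scaling, block of CREB by A-CREB, infection itself and a difference between single cultures stay open. The design has no control virus and 1 library per group.

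Genes below 1 FPKM were listed as over 2-fold in both tables. The worth of 1 read was fitted on a random part of these genes and scored on the rest, over 100 splits. In the glucose table a median of 51.9% of the held-out ratios lay on small whole-read ratios (lowest split 39.3%), against at most 21.0% when those ratios were shifted in 24 steps. In the A-CREB table it was 73.6%, against at most 20.1%. Many of these folds may therefore rest on a few reads. No biological explanation was tested.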

How the results depend on the processing

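No paired analysis was possible because each group had 1 library, and for the same reason no library could be left out in turn. Of 78 alternatives of the main counts, medians and shared-gene counts, 55 kept their value within 1.5 times (counts) or within the interval (medians) and 23 moved, none with a change of sign. The cause was not tested except where the setting itself takes out genes. With a pseudocount of 1 the median change was -0.63 with glucose and -0.82 with A-CREB, the median DMSO ratios were 0.066 and 0.17, and 289 genes without virus and 66 with A-CREB reached 2-fold. With a pseudocount of 0.01 the median changes were -0.88 and -1.34. At a mean of at least 5 FPKM the median change with glucose was -0.77, the A-CREB DMSO ratio was 0.014, and 252 and 63 genes reached 2-fold without virus and with A-CREB. At 1.5-fold 784 genes passed at 20 mM and 212 with A-CREB. At 3-fold 577 genes passed at 2.8 mM, 257 at 20 mM, 205 without virus and 51 with A-CREB. Among reference folds of at least 8, chosen after seeing the data, the median changes were -1.64 and -2.64. With lists matched on the reference fold, also chosen after seeing the data, 1 list lay at or below the 5th percentile of change in the glucose table (hypoxia and glycolysis) and 1 in the A-CREB table (growth factors), where 2 lay at or above the 95th (stress response and MAPK phosphatases). Both list settings that leave out genes, at 0 or below 1 FPKM, were added after seeing the data and changed these counts, with matching on mean expression, by at most 1 list. Single small lists were less stable, since the matched percentile of hypoxia and glycolysis with glucose, 4.84, was 5.28 with genes at 0 left out, which leaves no glucose list at or below the 5th, and 2.20 at a mean of at least 1 FPKM. At that mean the matched percentile of A-CREB growth factors was 7.11 and that of cAMP attenuators 1.86 instead of 75.7. With genes at 0 left out, the matched percentile of A-CREB growth factors was 0.91. In the same setting the DMSO ratio percentile of beta cell genes with glucose was 7.48. Of 236 values of change in named genes, 158 stayed close, 76 moved and 2 turned sign with a pseudocount of 1, Stc1 with glucose to -0.022 and Kcnf1 with A-CREB to 0.15. Rxfp3 in the A-CREB table, listed at 0 in A-CREB DMSO, also turned sign with a pseudocount of 0.01 and has no fold here. The alternative of genes marked significant by the authors was not run, since neither table has such a column, and no symbol was repeated. Depth limits genes below 1 FPKM, where 1 read is a large part of the value.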

Other observations

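The test in the last paragraph was chosen before its result was seen. The genes of the next paragraph were chosen after their values were seen, as exceptions within the fixed lists, and not all exceptions are given.

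Besides Egr1, Egr2 of the same zinc finger family had a higher forskolin fold at 20 mM than at 2.8 mM glucose, with a change of 1.46, but at 0.502 FPKM in 20 mM forskolin it lay at a level of few reads. The other 4 exceptions of the CREB early response list had nearly equal folds. Ier2 had 4.19-fold at 2.8 mM and 4.57-fold at 20 mM, Ier3 had 4.35 and 4.71, Per2 had 2.42 and 2.77, and Egr4 had 13.4 and 13.7. In the stress list, Hmox1, which encodes a heme-degrading enzyme, had folds of 3.07 and 4.66, and Chac1, which encodes a glutathione-degrading enzyme, had 2.90 and 3.98. Dusp4 was the exception of the MAPK phosphatase list, with 5.94 and 6.49, and Nkx2-2, a transcription factor of islet cells, had 2.01 and 2.17. With A-CREB, Gadd45b was the stress list's member with a clearly lower fold, at 5.92 without virus and 1.96 with A-CREB.

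Genes whose fold was lower with A-CREB could also be those whose fold was lower at 20 mM glucose. Given both reference folds and the mean level in the glucose table, the partial Spearman correlation across the 324 shared genes was 0.11 (95% bootstrap interval 0.0017 to 0.22). The mean level in the A-CREB table was not included. The interval reaches from near 0 to above the bound of 0.2 set in advance, so these data neither show nor exclude such a relation beyond the one the reference folds bring.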
